A study of Caenorhabditis elegans with 2 samples.

How the data were processed

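The data were ChIP-seq peak lists from 2 biological replicates (numbers 1 and 3) of whole young adult C. elegans expressing GFP-tagged B0261.1. The groups were taken from the labels, which name 1 strain, 1 stage and 1 time point, so there was no comparison between conditions. The labels name an antibody against GFP in the description and B0261.1 in the antibody field.

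Per the deposited file descriptions, the authors aligned each replicate to builds ce10 and ce11, called ranked peaks and background regions for each replicate and for both together against a control, and passed these lists to IDR. The aligner, the peak caller and the IDR threshold were not given in the sources used here. Each deposited region carries the authors' signal value, which has no stated normalisation and was used only within a list, to rank, describe, filter and test regions. A planned comparison of peak signal between the replicates is not reported here. The deposited −log10 q-value was read and not used for a test: it was 3.79 for every IDR peak. Regions in a list can overlap and share coordinates with different summits, as 400 of the 1550 IDR peaks did. Merging overlapping regions left 1280 sites of the IDR peaks, 975 of the top 1550 regions of replicate 1 and 1204 of those of replicate 3. The lists give no read depth, so depth could not set the precision; Wilson intervals at the 95% level cover counting of regions only. Control alignments were not used here.

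Coordinates are 1-based in ce11, which is the WBcel235 assembly of the reference. Genes came from the RefSeq annotation (WormBase release 298). The ce10 lists, of 1570 IDR peaks, gave counts only. A region was placed by its summit, within 100 bp of a gene for the noncoding classes and from 500 bp upstream to 100 bp downstream of the start for promoters. Classes followed the annotation's biotypes, with U6 genes taken as snRNA genes that hold a conserved U6 sequence. IDR peaks were compared with the 28470 pooled regions that had no summit within 100 bp of an IDR summit, which are the regions that could have passed. Of the IDR summits 1530 lay within 100 bp of a pooled summit, and 97.3% of the 1550 highest-signal pooled regions lay within 100 bp of an IDR summit.

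Shares were compared with two-sided Fisher's exact tests, adjusted by Benjamini and Hochberg over 13 classes, 23 gene lists or 2080 sequences of 6 bases (each with its reverse complement). Gene lists were tested among genes with any region in the promoter window. Medians of signal were compared with a two-sided permutation test of 100000 resamples. Values under 1e-300 were set to that bound. For each replicate, as many of its highest-signal regions as there are IDR peaks were compared with the rest of its list; around the tagged gene the whole list of each replicate was used. Tests, samples, gene lists and alternatives were fixed before the data were examined, except where the text says otherwise. Named were the 20 IDR peaks of highest signal, up to 4 peaks of each class and gene list by signal, the tagged gene and unc-119, and the 5 sequences of smallest adjusted p.

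The tests were run on simulated regions with planted answers. For the noncoding classes, 3 of 3 planted classes were called of 13, with 1 further class that overlaps a planted class. For the gene lists, 2 of 2 planted lists were called of 23, with 0 others. For the sequences of 6 bases, 3 of 3 planted were called of 2080, with 22 others, all of which overlap a planted sequence. With nothing planted, both sets were random genome positions, and 0 were called in each. Such positions lack the overlapping regions and the difference in G and C of the real lists. The 0 therefore gives no error rate for the real lists. A B box planted at 50% of summits was recovered at 53.3% with a background of 7.95%, and a signal made 4 times higher at tRNA genes was recovered as 4.37 times.

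Alternatives included the 775 IDR peaks of highest signal, other distances and windows, other backgrounds, leaving out tRNA peaks, each replicate's list alone, the ce10 lists and, added after the data were seen, 1 summit per site. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.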

Results

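Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where the protein of the C. elegans gene B0261.1 sits on the genome. The gene, listed in the annotation as vep-1, encodes a protein with a Myb-like domain, a fold found in many DNA-binding proteins. It lies on chromosome I from 5263694 to 5268380 on the plus strand (build ce11). Worms of strain OP662 carried a transgene encoding the protein with a C-terminal GFP-FLAG tag, and antibodies against GFP were used for the precipitation. Whole young adults were collected 64 hours after synchronisation as starved first-stage larvae. The samples formed 1 group of 2 biological replicates, numbered 1 and 3, so the comparisons were between peaks and background regions and between the replicates. Control libraries were not analysed here.

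The deposited lists for build ce11 held 23931 regions for replicate 1, 30000 for replicate 3 and 30000 for both replicates pooled. A further list held the 1550 peaks that passed the authors' threshold on the irreproducible discovery rate (IDR), a measure of reproducibility. Of these, 1421 had a region with a summit within 100 bp in both replicates' lists. No such region was found in replicate 1 for 88 peaks and in replicate 3 for 59. An IDR peak is therefore not always a summit found in both lists. The authors' signal value of the IDR peaks ran from 179 to 15652, with a median of 504. Read depth was not given in the lists, so the precision below rests on numbers of regions. The 28470 pooled regions with no summit within 100 bp of an IDR summit served as background. Tests across regions describe these lists, since regions are not replicates; the spread between the replicates' own lists is given as mean ± SD (n = 2).

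The strongest sites were shared between the replicates. M02F4.t1, a tRNA-Gly gene on X from 3036164 to 3036235, had the top region in both replicates and in the pooled list, with a pooled signal of 15652. Of the 1550 highest-signal regions of replicate 1, 1150 (74.2%, 95% Wilson interval 72.0 to 76.3%) had a summit within 100 bp of a summit among the 1550 highest of replicate 3. Random sets of as many regions drawn from each list shared a mean of 1.52% (0.839 to 2.32% over 100 draws). Among regions of replicate 1 at tRNA genes 89.3% were shared (503 of 563), against 65.6% of the others (647 of 987). The overlap was 47.7% for the top 5000 regions of each list.

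Transfer RNA (tRNA) genes had far more peaks than background, and the strongest single peak lay at a tRNA gene. Of the 1550 IDR peaks, 513 (33.1%, Wilson interval 30.8 to 35.5%) had a summit within 100 bp of an annotated tRNA gene, against 25 of 28470 background regions (0.0878%). The share was 34.6% ± 2.42 (SD, n = 2) in the replicates' own lists, 36.3% in replicate 1 and 32.9% in replicate 3. The two-sided Fisher's exact test gave a p below 1e-300, the smallest value printed here. Of the 612 nuclear tRNA genes, 524 had a peak (85.6%, Wilson interval 82.6 to 88.2%), while 64 of 19971 protein-coding genes (0.320%) had a peak within 100 bp of their start. These windows differ: tRNA genes were counted over the whole gene with 100 bp on each side, protein-coding genes only around the annotated start. Annotated starts in this organism are often trans-splice sites. From 500 bp upstream to 100 bp downstream of the start, 367 protein-coding genes had a peak. The replicates' lists gave 85.1% ± 0.693 (SD, n = 2) of tRNA genes, and 506 of these genes had a peak in both lists. With a distance of 25 bp in place of 100 bp, 17.5% of peaks lay at tRNA genes, fewer than at unclassified noncoding RNA genes (20.1%), and 44.4% of tRNA genes had a peak. Of the 775 IDR peaks of highest signal 62.5% lay at tRNA genes.

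Occupied tRNA genes were found for every isotype in the annotation. All 12 tRNA-Trp genes and the single tRNA-Sec gene had a peak, as did 32 of 34 tRNA-Thr and 29 of 31 tRNA-Val genes. The lowest shares among named isotypes were those of tRNA-His (12 of 20) and tRNA-Met (14 of 20). Of 5 genes with no isotype named in the annotation, 1 had a peak. Among named isotypes the median signal of occupied genes ran from 808 for tRNA-Sec and 1375 for tRNA-Pro to 3122 for tRNA-Asp. These isotype counts were not tested against each other.

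The signal of peaks at tRNA genes had a median of 2510, against 302 for the other 1037 IDR peaks. The medians differed by 2208 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The same direction was found in replicate 1 (421 against 104) and in replicate 3 (2095 against 279), each on its own scale of signal. Among the 155 peaks of highest signal 76.8% lay at tRNA genes, and among the 155 of lowest signal 0.645% did.

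**Figure D1:**
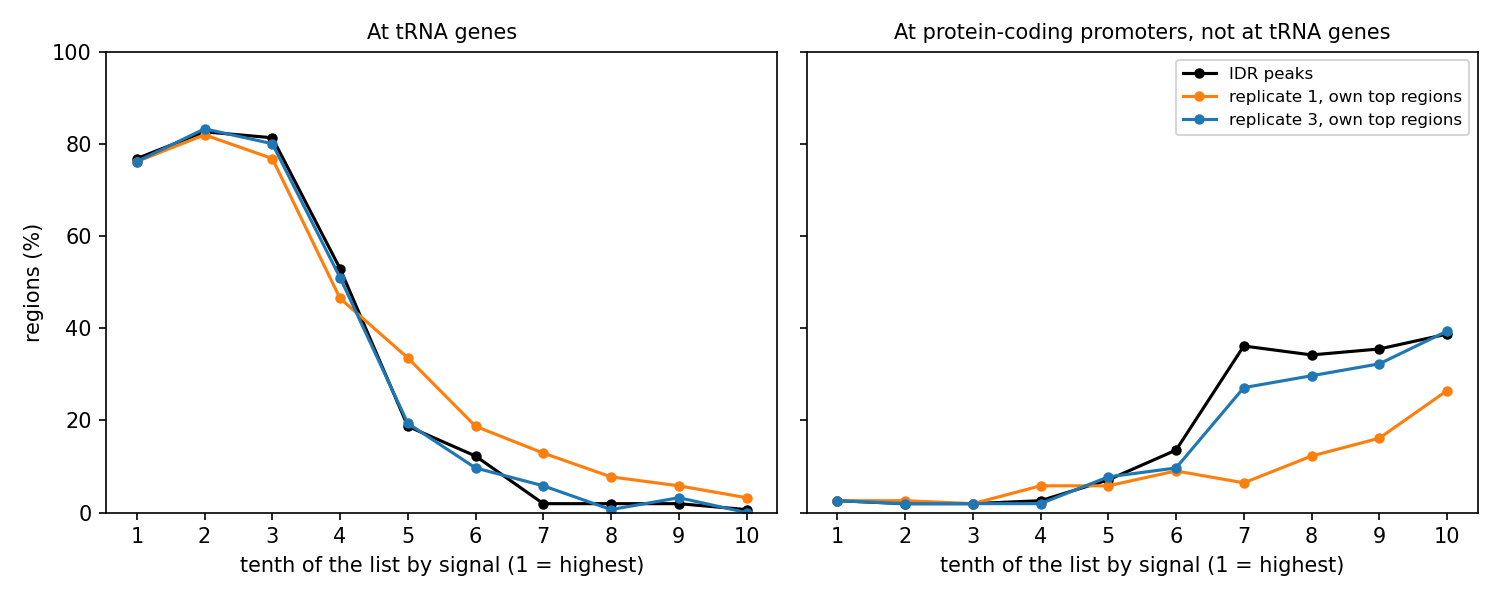
Share of regions at tRNA genes (left) and at protein-coding promoters but not at tRNA genes (right), in percent, in 10 bins of each list from highest to lowest signal. Lines show the IDR peaks and the 1550 highest-signal regions of each replicate; at tRNA genes the share of IDR peaks went from 76.8% to 0.645%, and at promoters from 2.58% to 38.7%.

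Of the 20 IDR peaks with the highest signal, 13 lay at tRNA genes and 7 at genes of small nucleolar RNAs (snoRNAs), which guide chemical modification of other RNAs. After M02F4.t1, the strongest were at F47G6.t1 (tRNA-Arg), in an intron of spe-15 on I with its summit at 1447081, C53C7.t2 (tRNA-Ser) on X at 13046505, and F15G9.t1 (tRNA-Ala), in an intron of him-4 on X at 9743667. Their signals were 11979, 10978 and 9468. The others at tRNA genes were at C28G1.t1 (tRNA-Glu), T23F1.t1 and W03G11.t1 (tRNA-Lys), F46G11.t2 and W09D6.t2 (tRNA-Pro), R11.t1 (tRNA-Tyr), C04A11.t1 (tRNA-Leu), F41D9.t3 (tRNA-Asn) and F42A10.t1 (tRNA-Ser). The strongest at a snoRNA gene, W03C9.9, had its summit on II at 11960799 and a signal of 8413. T03F7.8 lay in an intron of cutl-18 on V (summit 11314177, signal 7526), T06C12.16 outside protein-coding genes on V (15874007, 7449) and ZK265.10 outside them on I (8259591, 7063). The other 3 were C51F7.4 and F55A11.10, with summits in coding exons of frm-7 and F55A11.6, and ZK994.7, in an intron of pxn-1. All 20 ranked 36 or better in both replicates' own lists.

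Other classes of small noncoding genes also had more peaks than background. Of 13 classes, 9 passed with more peaks (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). At snoRNA genes lay 75 peaks (4.84% against 0.358% of background regions, exact test, adjusted p = 2.05e-48), and 75 of 346 snoRNA genes had one. At tRNA pseudogenes lay 35 peaks (2.26% against 0.295%, exact test, adjusted p = 4.78e-17). At genes of U6, the spliceosomal RNA made by RNA polymerase III, lay 12 peaks (0.774% against 0.0281%, exact test, adjusted p = 7.66e-11), and 8 of 22 U6 genes had one, as in each replicate's list. SL RNA genes, which supply the leader that is spliced onto many messenger RNAs, had 7 peaks at 6 of 30 genes (exact test, adjusted p = 2.20e-05), and 5S rRNA genes 3 peaks at 2 of 16 genes (exact test, adjusted p = 0.000859). Against the 1550 regions ranked just below the IDR peaks 5 classes passed with more peaks: tRNA genes, tRNA pseudogenes, U6, snoRNA and unclassified noncoding RNA genes. With summits within 25 bp 6 classes passed with more peaks, and U6, 5S rRNA and microRNA genes did not (exact test, adjusted p = 0.109, 1 and 0.0535). With the 775 IDR peaks of highest signal 6 passed, and 5S rRNA, other snRNA and microRNA genes did not (exact test, adjusted p = 0.0971, 0.461 and 0.128).

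The remaining classes that passed were by the exact test other snRNA genes (13 peaks, adjusted p = 1.36e-05), microRNA genes (7 peaks, adjusted p = 0.00768) and unclassified noncoding RNAs (433 peaks, 27.9% against 4.31%). Without the peaks at tRNA genes the last of these had 125 of 1037 peaks (12.1%, exact test, adjusted p = 2.01e-22), a count chosen after the data were seen. In replicate 1 alone the other snRNA and microRNA classes did not pass the exact test (adjusted p = 0.234 and 0.425), and against the regions ranked just below the IDR peaks the other snRNA share turned lower (0.839% against 1.35%, adjusted p = 0.406). Genes of piRNAs had fewer peaks than background (0.387% against 0.962%, exact test, adjusted p = 0.0258), which did not hold in either replicate's list (adjusted p = 0.490 and 0.860). Long intergenic and antisense RNA genes had 3 peaks each and were not shown to differ from background, and no peak lay at the 4 other rRNA genes.

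Within these classes, the strongest peaks were at the tRNA pseudogenes D1046.t1 (signal 5398), Y69A2AR.t1 (4152), C52E12.t1 (3442) and T08B2.t1 (3064), all in introns. The U6 genes W05B2.8, F54D8.7, C28A5.7 and R07E5.16, all on III, had signals of 3143, 2077, 1106 and 934; replicate 1 had no summit within 100 bp of that at R07E5.16. The SL RNA genes sls-2.9, sls-2.1, sls-2.4 and sls-2.2 had signals of 2936, 785, 615 and 545, and the peak near sls-2.9 also lay within 100 bp of a tRNA gene. The 5S rRNA gene rrn-4.15 on V had 850 and rrn-4.12 had 195. The microRNA genes mir-4936, mir-2214, mir-1829.3 and mir-4937 had 3897, 2666, 660 and 372. The snRNA genes M163.13, sup-6 and Y69A2AR.36 had 1418, 583 and 453. The strongest peaks of several other classes also lay within 100 bp of a tRNA gene, and no test separated the neighbouring genes: those near the piRNA genes 21ur-5229, 21ur-3160, 21ur-753 and 21ur-11419, near the unclassified noncoding RNAs M02F4.12, F47G6.6, F15G9.8 and C28G1.8, and near the antisense RNA W10G6.5. The antisense RNA anr-20 had 385 and the long intergenic RNAs K07C10.8, linc-128 and linc-7 had 359, 314 and 251, the peak in K07C10.8 being also within 100 bp of a snoRNA gene.

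**Figure D2:**
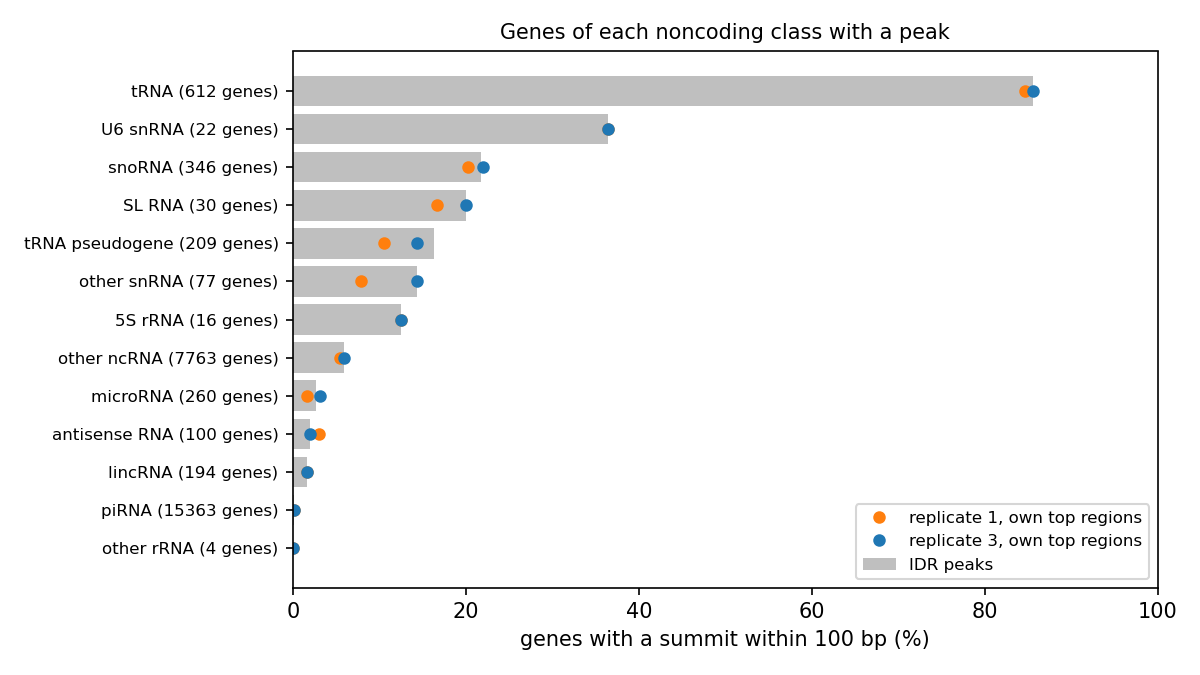
Share of the genes of each noncoding class with a summit within 100 bp, in percent. Bars show the IDR peaks and points the 1550 highest-signal regions of each replicate; tRNA genes reached 85.6%, U6 genes 36.4% and snoRNA genes 21.7%.

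The summits lay upstream of the tRNA and snoRNA genes, at different distances. This measure was chosen after the data were seen. For 477 of 551 tRNA genes with a summit within 300 bp (86.6%), the summit nearest to the first base lay upstream. Genes were counted here, and neighbouring genes can share a summit. The median position was -25 bp from the first base of the gene (95% bootstrap interval over genes -26 to -24). It was -26 bp in replicate 1 and -25 bp in replicate 3. In 474 of the 612 tRNA genes no 31-base sequence of the gene occurs once in the genome. For 84 snoRNA genes it was -81.5 bp (interval -83.5 to -77), and for 8 U6 genes -28.5 bp (interval -44 to -22; in replicate 1 -27.5 bp, interval -32 to 75). The snoRNA and tRNA medians differed by -56.5 bp (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give), and in the replicates' own lists the snoRNA medians were -82 and -81.5 bp.

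**Figure D3:**
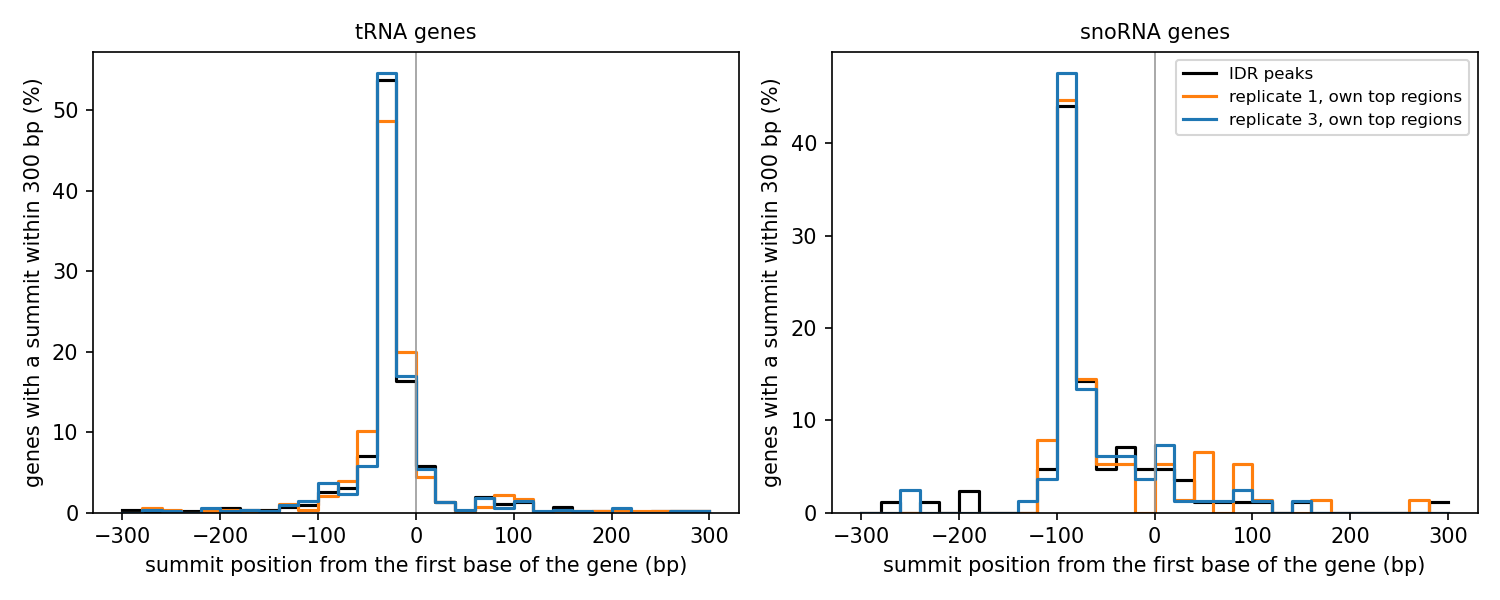
Position of the summit nearest to the first base of each tRNA gene (left) and snoRNA gene (right), in bp along the gene's strand in bins of 20 bp, as the percent of genes with a summit within 300 bp. Lines show the IDR peaks and each replicate's 1550 highest-signal regions; the medians of the IDR peaks were -25 bp and -81.5 bp.

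The B box, part of the internal promoter of tRNA genes, was frequent within 100 bp of the summits and much less so within 50 bp. Its consensus GWTCRANNC occurred within 100 bp of 766 of 1550 IDR summits (49.4%, Wilson interval 46.9 to 51.9%) and of 9.25% of background summits (two-sided Fisher's exact test, p below 1e-300). The share was 46.8% ± 2.69 (SD, n = 2) in the replicates' own lists. Among the 1037 peaks with a summit over 100 bp from tRNA genes it was 30.8% (exact test, p = 4.96e-80). Some of these still lay near tRNA genes, since 33.1% of IDR peaks had a summit within 100 bp of one and 38.6% within 250 bp. This also holds for the other values without the peaks at tRNA genes. Within 50 bp of the summit it was 9.10% against 4.71% (p = 2.41e-12 by the exact test). By place, 22 of 35 peaks at tRNA pseudogenes and 33 of 72 at snoRNA genes had the sequence, while 23 of 254 peaks at protein-coding promoters did (9.06%).

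Of 2080 sequences of 6 bases, 422 were at least 1.5 times as frequent within 50 bp of IDR summits as at background summits (two-sided Fisher's exact tests, adjusted p under 0.05). The smallest adjusted p-values belonged to ACCACT (19.8% of peaks against 3.76%), CGGCCA (14.5% against 2.76%), GGCCGA (12.6% against 2.63%), TAACCA (12.8% against 2.80%) and CCACTA (12.3% against 2.64%). Many peaks lay at tRNA genes, and in 474 of 612 of these no 31-base sequence of the gene occurs once in the genome. The test counts such copies as separate peaks, so over all peaks it cannot separate these sequences from tRNA gene sequence. Without the peaks at tRNA genes 357 passed, led by CGGCCA, CGCGCA, GGCCGA, CACTCG and GCGCAC. The windows held 45.3% G and C at IDR peaks and 39.7% at background regions. Against the 1550 regions ranked just below the IDR peaks, 136 passed.

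Peaks at protein-coding promoters were weaker and less often shared than those at tRNA genes. From 500 bp upstream to 100 bp downstream of a gene start lay 322 IDR peaks (20.8%, Wilson interval 18.8 to 22.9%), against 17.8% of background regions (two-sided Fisher's exact test, p = 0.00387). The 254 promoter peaks not at tRNA genes, tRNA pseudogenes or snoRNA, snRNA, SL RNA or 5S rRNA genes had a median signal of 238, and 36.2% of them were found in the top list of replicate 1, 79.1% in that of replicate 3 and 31.5% in both. Of the peaks at tRNA genes 95.3% were found in both. These shares depend on a rank cut that weaker peaks miss more easily, and peaks of equal signal were not compared. They are therefore no separate measure of reproducibility. The promoter share did not hold in both replicates: it was 18.8% against 18.0% in replicate 3 (exact test, p = 0.396) and 12.5% against 16.8% in replicate 1 (p = 4.89e-06), where the direction turned. Among the 775 IDR peaks of highest signal it was 9.55%, below the background, as it was in a window from 200 bp upstream (9.35% against 10.8%) and against the regions ranked just below the IDR peaks (20.8% against 35.0%). With overlapping regions merged to 1 summit per site and 1280 sites taken from each list, which reached further down that of replicate 1, a setting chosen after the data were seen, both replicates were above their backgrounds (19.8% against 16.3% in replicate 1 and 23.1% against 18.0% in replicate 3). Without the peaks at tRNA genes the share was 26.0% (exact test, p = 1.24e-10), but in replicate 1 it was then 14.0%, below its background (exact test, p = 0.0207).

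Among 23 lists of protein-coding genes, the cytosolic ribosomal proteins, which build the ribosome, had more peaks than other genes. Of 65 members with any region in the promoter window, 19 had an IDR peak (29.2%), against 348 of 4926 other genes (7.06%; two-sided Fisher's exact test, adjusted p = 2.24e-06). The difference held in replicate 3 (17 of 65, exact test, adjusted p = 2.52e-05) and in replicate 1 (11 of 54, adjusted p = 0.000937). The strongest were rpl-15 on IV (signal 797), rpl-35 (710), rpl-3 (677) and rps-3A (558) on III, with summits from -444 to -263 bp from the annotated start. With the 775 IDR peaks of highest signal alone, 0 lists passed, and 4 of 54 ribosomal protein genes had a peak (7.41%, against 1.45% of other genes; exact test, adjusted p = 0.200). With all protein-coding genes as background 5 lists passed with more peaks, the others being translation factors, splicing factors, heat shock genes and the respiratory chain. Among genes with a region, these had peaks at 0 of 12, 0 of 13, 3 of 8 and 1 of 22 members in replicate 1. In replicate 3 the counts were 5 of 27, 4 of 18, 4 of 13 and 4 of 25. With all genes as background 2 lists passed with fewer peaks. These were the chemoreceptors (0.570% against 1.92%, exact test, adjusted p = 0.00186) and the F-box genes (0 of 322 against 1.87%, exact test, adjusted p = 0.0168).

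No other list passed among genes with a region. By the exact test, the heat shock genes had 4 of 12 (adjusted p = 0.102): hsp-1, hsp-90, hsp-3 and hsp-110, with signals of 381, 366, 303 and 271. The peak of hsp-110 was also that of rpn-3. The splicing factors had 5 of 21 (exact test, adjusted p = 0.122; snr-4, snr-1, prp-8 and rsp-2 the strongest, that of snr-4 at an snRNA, SL RNA or 5S rRNA gene). The translation factors had 5 of 26 (iff-2, eef-1A.2, eef-2 and eef-1A.1) and the respiratory chain and ATP synthase 5 of 26 (atp-1, cox-5B, cox-5A and ucr-2.2), both with adjusted p = 0.169 by the exact test. Replicate 1 had no summit within 100 bp of those at eef-2, eef-1A.1 and snr-4. The chemoreceptors had 7 of 45 (15.6% against 7.28%, exact test, adjusted p = 0.169), the direction opposite to that with all genes as background, and the strongest of these peaks, near srh-269, srd-44 and srz-58, lay at tRNA genes and that near srz-97 at an snRNA, SL RNA or 5S rRNA gene. The proteasome had 2 of 22 (rpn-3 and rpn-11). A single member had a peak among the mitochondrial ribosomal proteins (mrpl-32, of 41), histones (his-37, of 17), collagens (col-40, of 19), aminoacyl-tRNA synthetases (ears-2, of 17), RNA polymerase subunits (rpb-11, of 16), nuclear hormone receptors (nhr-68, of 58), homeobox genes (ceh-43, of 12), C-type lectins (clec-126, of 18) and germline genes (cpg-1, of 9). The peaks near ceh-43 and clec-126 lay at tRNA genes, and that of nhr-68 ranked 22750 in replicate 1. The F-box genes had 0 of 28, the cytochrome P450 genes 0 of 7, the intestine list 0 of 7, the body muscle list 0 of 6, the neuron list 0 of 3 and the major sperm proteins 0 of 1, and no hypodermis gene could be tested.

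The X chromosome held 455 of the 1550 IDR peaks (29.4%, Wilson interval 27.1 to 31.7%), against 5991 of the 28470 background regions (two-sided Fisher's exact test, p = 6.86e-14). In the replicates' own lists the share was 30.8% ± 1.87 (SD, n = 2). Of the 612 tRNA genes 276 lie on X, and 232 of these had a peak; on the other chromosomes 48 to 69 tRNA genes had one. Without the peaks at tRNA genes, 22.4% of IDR peaks were on X (exact test, p = 0.314). That share was 22.2% in replicate 3 (exact test, p = 0.417) and 25.5% in replicate 1 (p = 1.13e-06), a difference that was not tested.

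The tagged gene itself and unc-119, which is mutant in this strain, did not have more regions than most windows. They were checked because the transgene was taken to carry further copies of both loci, which add reads there whatever the protein binds. Within 20 kb of the centre of vep-1 lay 7 pooled regions, more than in 30.4% of 2503 windows of the same width (median 11 regions), and no IDR peak. The replicates' lists had 6 and 9 regions there. All 7 pooled regions lay to the right of vep-1, whose nearest pooled summits were 80883 bp to its left and 4368 bp to its right. On the left the nearest summit was 51574 bp away in replicate 1 and 80533 bp away in replicate 3. At unc-119, which lies on III from 10902641 to 10908935, there was no region within 20 kb in the pooled list or in either replicate's list. Whether either locus was masked, or its reads set off by the control, is not given in the sources used here. The 0 at unc-119 and the count at vep-1 are therefore no measure of binding there. The pooled summits nearest to unc-119 were 33583 bp to its left and 27311 bp to its right.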

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

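The settings without tRNA peaks for classes and gene lists, with 1 summit per site, with any pooled region, those that drop a replicate together with another choice and the ranks of named peaks were chosen after the data were seen. The share of peaks at tRNA genes, the share of tRNA genes with a peak, the signal difference and the B box share kept their direction and side of the threshold under every alternative run. The tRNA share was lowest with summits within 25 bp (17.5%) and highest for the 775 strongest peaks (62.5%). In all, 65 of the settings tried were kept, 9 moved the value, 5 turned the direction and 3 kept the direction without passing the threshold. Kept means the same call or, for counts, within 1.5 times the count, even where single classes dropped out. Replicate overlap was kept inside the Wilson interval of its main value. The percentile at the tagged gene was kept within the SD of the replicates around its main value. That SD came from the same replicate values, so leaving out a replicate tests little there.

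Overlap of the replicates' top regions was 69.4% within 50 bp, 95.9% within 250 bp, 86.0% for regions overlapping by 50% of each, 80.5% for the top 775 regions and 47.7% for 5000. The 9 classes with more peaks became 6 with summits within 25 bp and 6 with the strongest 775 peaks; 7 to 9 passed without a replicate. Against the next-ranked regions 5 classes and 136 sequences of 6 bases passed. Of the gene lists, 0 passed with the strongest 775 peaks (ribosomal proteins 7.41% against 1.45%) and with all protein-coding genes as background 5 passed with more peaks and 2 with fewer (chemoreceptors 0.570% against 1.92%, F-box genes 0% against 1.87%).

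The promoter share turned for the 775 strongest peaks (9.55%), against the next-ranked regions (20.8% against 35.0%) and in a window from 200 bp upstream (9.35% against 10.8%). Leaving out a replicate gave 12.5 to 18.8%, and with tRNA peaks also left out 14.0% without replicate 3 (below its background of 16.8%) to 23.0% without replicate 1 (above its 18.0%). It stayed higher than background without tRNA peaks (26.0%), against random positions (20.8% against 10.7%) and in a wider window (30.6% against 28.3%). With 1 summit per site it gave 19.8 to 23.1%, each above its background. The X share without tRNA peaks was 22.4%, and 22.2 to 25.5% with a replicate also left out. The cause of these changes was not tested, except that 3 causes of the promoter difference between the replicates were. Of 76 peaks named by class or gene list, 52 were among the top 1550 regions of replicate 1 and 72 among those of replicate 3 (52 in both). Read depth is unknown, which limits what the weaker peaks can show.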

Other observations

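All tests in this part were chosen after the data were seen; of these, the median unique-sequence share and the B box test of tRNA genes without a peak and the promoter difference with 1 summit per site and 1280 sites each were set out before their own results were seen.

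Peaks outside promoters and not at tRNA genes, tRNA pseudogenes or snoRNA, snRNA, SL RNA or 5S rRNA genes also carried the B box. Among 196 such peaks in the 775 strongest, 95 had it (48.5%), against 144 of 446 in the others (32.3%; two-sided Fisher's exact test, p = 0.000131). Of these peaks, 29 and 35 lay at unclassified noncoding RNA genes, and some lay at microRNA genes. The 5 strongest, chosen after their values were seen, lay at the pseudogene T26C11.3 on X (summit 1837919, signal 4719, no B box), in the noncoding RNA Y69A2AR.37 on IV (2664981, 4635), in srt-52 on V (53457, 4522), in the noncoding RNA K10H10.14 on II (14496984, 4197) and 77 bp from unc-45 on III (502702, 3906), the last 4 with the B box. Among snoRNA genes, 27 of 75 with a peak had a B box within 150 bp upstream (36.0%), against 25 of 271 without (9.23%; two-sided Fisher's exact test, p = 1.29e-07). Shares inside protein-coding genes were not shown to differ (58.7% and 62.4%, Fisher's exact test, p = 0.593). IDR summits were rare in coding exons (5.35%, against 27.4% of background) and 46.4% of those at tRNA genes were in introns.

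The summits at tRNA genes lay upstream of the gene: around 442 tRNA genes with no other within 500 bp, 362 summits lay within 100 bp upstream, 36 inside the gene and 12 within 100 bp downstream (88.3% upstream, Wilson interval 84.8 to 91.1%). A fixed shift of coordinates was argued against, since it would change sign with the strand and the median was -24.5 bp for plus-strand and -25 bp for minus-strand genes. Loss of reads inside near-identical tRNA copies would by itself favour neither flank. For these genes, 362 summits upstream against 12 downstream argue against it as the only cause of the upstream side. Whether it moved summits out of the gene cannot be told apart from the position of the protein. In 474 of 612 tRNA genes no 31-base sequence of the gene occurs once in the genome. In the 8 genes with a summit where every such sequence does, the median was -4 bp (bootstrap interval -34 to 34). Where at least 50% do it was -23 bp (57 genes, -26 to -19), and where none does -25 bp (454 genes, -26 to -25). How the caller places summits was not tested, and no biological explanation of this position was tested.

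Of 88 tRNA genes without an IDR summit within 100 bp, called genes without a peak here, 22 had a pooled summit within that distance. Their number depends on the rule. Of the 612 tRNA genes, 85.6% had an IDR summit within 100 bp and 89.7% within 250 bp, and an IDR region overlapped 92.8%. Part of the 88 therefore follows from the summit rule. The share of 31-base sequences that occur once was taken here over the gene and 100 bp on each side, not over the gene alone. On this measure repeated sequence around the gene was argued against as a general cause. The median share differed by 0.618 percentage points from that of genes with a peak (bootstrap interval -0.826 to 3.21). Genes with and without a peak were not compared by the sequence of the gene alone. In a minority repeated sequence around the gene may matter. By this share 11 (12.5%) were under 50% unique, against 2.67% of genes with a peak (two-sided Fisher's exact test, p = 0.000239). The B box was present in 93.2% of genes without and 99.4% of genes with a peak (Fisher's exact test, p = 0.000442), so its absence could account for 6 genes at most. Of 579 genes with the B box and at least 50% unique sequence over the gene and its flanks 507 had a peak by the 100 bp rule. The rest stay open, and those overlapped by an IDR region were not counted apart.

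The promoter share of the top 1550 regions was 6.39 percentage points higher in replicate 3 than in replicate 1. A larger number of tRNA regions in replicate 1 was argued against, since the difference was 9.0 points without them (95% interval 5.65 to 12.3). Merging overlapping regions, which left 975 and 1204 sites, did not lower it (7.38 points, 4.17 to 10.6), while equal numbers of sites gave 2.15 points (-1.06 to 5.37) with 975 and 3.36 points (0.182 to 6.54) with 1280 each. Several summits at a site and a shallower list in replicate 1 cannot be told apart, since the promoter share rose down both lists and these settings also change how far down each list is read. For the same reason the difference of -2.40 points (-7.46 to 2.66) among the 250 strongest regions with a summit over 100 bp from tRNA genes decides nothing. No biological explanation was tested.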
